A study of Mus musculus with 35 samples.

How the data were processed

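Bulk RNA sequencing of mouse microglia was analysed from 3 deposited tables. Cells had been sorted by flow cytometry on CD11b and CD45, with exclusion of dead cells, after myelin removal on a Percoll gradient, per the labels' protocols. Libraries had been made with a full-length ultra-low-input cDNA kit and a transposase-based library kit, which do not mark the strand, and were sequenced with paired ends, per the labels' protocols. Reads of a gene and of an antisense gene that overlaps it cannot be told apart in such libraries. The kits carry no molecular identifiers named in the labels, so counting precision refers to sequenced fragments and not to molecules.

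The authors deposited expected counts, which are estimated fragments per gene and need not be whole, for 45706 genes and 35 libraries. RSEM and DESeq2 are named, with the build mm10, per the submitters' processing notes, and their versions and settings are not given in the sources used here. The table held no spike-in genes and was not normalized, as judged from totals that differ between libraries. Of its values, 84.67% were whole within a tolerance of 1e-6, and all were rounded to whole numbers before any count test. RSEM shares reads among near-identical copies by estimation, so values of multigene families and of genes with many processed pseudogenes, ribosomal protein genes above all, carry that uncertainty. The authors also deposited TPM values for the same genes. Their columns summed to less than the full TPM total, and the missing share, here called the TPM share outside the table, was 8.42 ± 6.76% (SD, n = 35 libraries). What made up that share is not given in the sources used here. A deposited design table gave a count of effective alignments per library, 38.4 M to 52.7 M (M, 1e6 alignments), a date code and the sex of each mouse. Other files listed no measurement and were not used here.

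Gene symbols were matched by identifier for 45143 of the 45706 genes, and the 563 others held at most 0.146% of the counts of any library. Coordinates are those of the GENCODE annotation on the mm10 build, matched by identifier without its version number.

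Groups were taken from the phenotype label of each sample. Controls comprised 6 rNLS8 mice kept on doxycycline and 8 wild-type mice. Labels describe each library as one mouse of its group. Counts of replicate libraries were compared by chi-square per gene over genes with at least 20 summed counts. Every pair within a group differed by far more than counting noise, which by itself does not show that they came from separate mice. Each library counted once, following the labels. The sex in the sample labels disagreed with Xist and Ddx3y counts in 2 libraries, Controls 7 and 8, where the deposited design table had the other sex. The sex in the labels was kept in the main test and the design table's sex was an alternative.

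Differences between groups were tested with edgeR 4.0.16 in R 4.3.3, using a quasi-likelihood F test on rounded counts, TMM normalization, the package's filter on low counts by group, and a model of group and sex over all 35 libraries. The filter kept 13501 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with standard errors derived from the F statistic, and expression as CPM, the count scaled to the TMM-adjusted library size, with SD over libraries. Within the controls, rNLS8 mice on doxycycline were compared with wild-type mice in a fit of the 14 controls, and an interaction of sex and group was tested for each group against control. Alternatives were DESeq2 1.42.0 and limma 3.58.1 on log2 of the deposited TPM plus 1 or plus 0.1, over genes with a TPM of at least 1 in 6 or more libraries.

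Before the data were examined, the groups, tests, 31 gene lists and the rule for naming genes were fixed. The 16 lists of cell states were homeostatic microglia, disease-associated microglia, proliferation, interferon response, antigen presentation, inflammatory cytokines and NF-kB targets, immediate early and stress genes, lysosome and phagocytosis, complement, cholesterol synthesis, lipid efflux and storage, growth factors, glycolysis, TGF-beta targets, p53 and apoptosis genes, and unfolded protein response. The 12 lists of other cells the gate could hold were monocyte, border macrophage, neutrophil, T and NK cell, B cell, oligodendrocyte, oligodendrocyte precursor, astrocyte, neuron, endothelial, mural and fibroblast, and erythroid markers. The 3 lists formed by gene name were ribosomal proteins, nuclear-encoded oxidative phosphorylation and mitochondrially encoded genes. Lists were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the 28 lists that had at least 3 tested genes, and again with the correlation estimated from the data. The lists of T and NK cells, oligodendrocyte precursors, and mural cells and fibroblasts had fewer than 3 tested genes and gave no result. Several markers are shared between lists or expressed by microglia as well. For each comparison the text could name the 8 genes with the largest rise and fall among called genes with a mean of at least 10 CPM in the higher group, the 3 members of smallest p in lists that were called or held at least 3 called genes, and Tardbp, Itgam, Ptprc, P2ry12, Tmem119, Cx3cr1, Trem2, Apoe and Mki67. Predicted and clone names were left out, as were genes whose group medians differed in the other direction or by under 0.5 of the fitted size.

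The code of 4 digits that opens each sample title equals the date in the deposited design table. All 7 recovery libraries and no others have the code 0803. The code 0810 holds Controls 1 to 9 alone, and the codes 1019, 1102 and 1130 hold early and late disease, with 5 controls in 1019 and 1102. Date was therefore not in the main model. Early and late disease against control were also fitted with date as a term and against the controls of shared dates, and late against early disease with date as a term. No such fit exists for the 2 comparisons of recovery, whose date no other group shares. For the kinds of control no fit had date as a term. They were also compared within the code 0810 alone, with a result not reported here.

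The steps were tested on simulated counts drawn from the means and library sizes of the real libraries, with 200 genes changed. At a simulated fold of 4, edgeR recovered 77.9% of the changed genes for early disease against control over 13275 genes, 84.1% for late disease against control over 13267, 83.3% for recovery against control over 13269, 80.6% for late against early disease over 13258 and 82.4% for recovery against late disease over 13269. At a fold of 1.5 it recovered 44.1%, 44.4%, 45.3%, 25.0% and 38.2% in the same order. False calls were 7, 6, 4, 2 and 9. For rNLS8 mice on doxycycline against wild-type controls 69.5% were recovered at a fold of 4 over 12408 genes.

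Other alternatives were another size factor method, no filter on low counts, no sex term, a fit of only the compared groups, the replicate number as a block, subsets of the controls, and each library left out in turn. Chosen after the data were seen were the sex of the design table, leaving out LateDisease 6 and Control 7 together, the mean of the neutrophil markers or the log2 TPM share outside the table as a covariate, TPM rescaled to a common total per library, and early disease against the controls of shared dates. Results of some single genes are not reported here.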

Results

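Microglia were profiled from the whole spinal cord of rNLS8 mice, a model of amyotrophic lateral sclerosis, and of wild-type (WT) littermates. In rNLS8 mice a neuronal promoter drives a human TDP-43 that lacks its nuclear localisation signal, and dietary doxycycline keeps the transgene silent. The 35 libraries comprised 7 of early disease (2 weeks without doxycycline), 7 of late disease (6 weeks without it), 7 of recovery (6 weeks without it, then 1 week with it) and 14 controls. The controls were 6 rNLS8 mice kept on doxycycline, 4 WT mice without doxycycline for 2 weeks, 1 for 6 weeks and 3 returned to it for 1 week after 6 weeks. Total expected counts ran from 13.9 M to 20.4 M per library (M, 1e6 fragments) and genes with any count from 14117 to 17308. Itgam and Ptprc, which encode the sorting antigens CD11b and CD45, stood at 1555 ± 316 and 421 ± 59.9 CPM in controls (SD, n = 14). The TPM share outside the deposited table was 18.3 ± 5.74% in the 9 controls of date code 0810 and 4.99 ± 1.99% in the 26 other libraries.

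**Figure D1:**
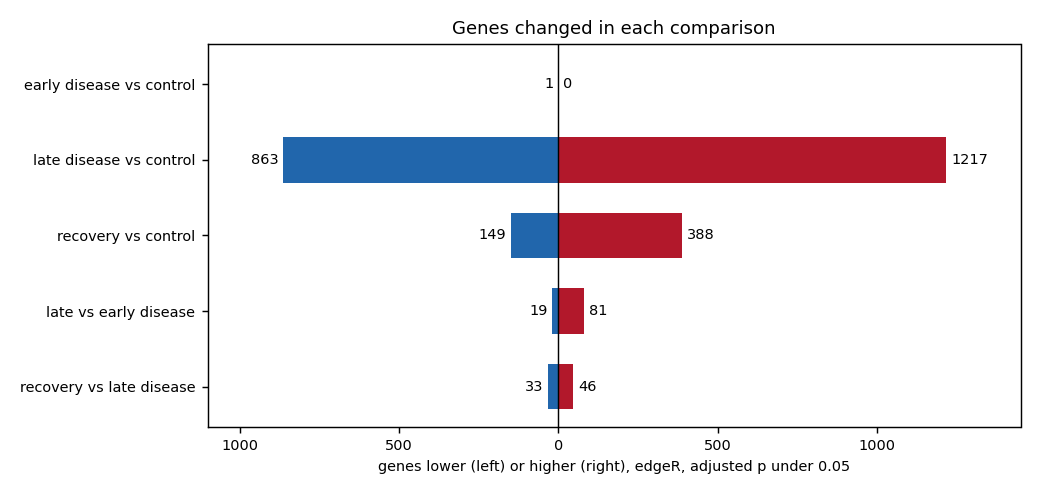
Number of genes lower (left bars) and higher (right bars) in the first-named group of each comparison, by edgeR at an adjusted p under 0.05 over 13501 genes. Late disease against control gave 1217 higher and 863 lower genes, and early disease against control gave 0 and 1.

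The first comparison asked what had changed in microglia after 2 weeks of transgene expression. A single gene passed the test. Akap9 (ENSMUSG00000040407.15, chromosome 5, 3928054 to 4081310), which encodes an anchoring protein for kinase A at the centrosome and Golgi, fell by 0.62 ± 0.11 (SE) on the log2 scale. Its level was 43.3 ± 4.59 CPM in early disease (SD, n = 7) and 66.5 ± 12.3 CPM in controls (n = 14), with an adjusted p of 0.0464 by edgeR's quasi-likelihood test. The microglial identity genes P2ry12 and Tmem119 differed by −0.19 ± 0.15 and −0.34 ± 0.09, with adjusted p of 0.637 and 0.113. Of the 13 mitochondrially encoded genes, 0 passed over all genes tested and 10 fell adjusted over the list alone, with a median log2 change of −0.46. mt-Nd4, a complex I subunit, was at 322 ± 63.6 CPM against 462 ± 103. The proliferation list had 0 of 40 genes past the test by edgeR, 0 adjusted over the list alone, 10 at an unadjusted p under 0.05 and a median of 0.69. The interferon response list and the inflammatory cytokine list had medians of 0.47 and 0.39 and also 0 genes past the test (0 and 2 adjusted over the list alone), with 8 each at an unadjusted p under 0.05. Nuclear-encoded oxidative phosphorylation genes had a median of −0.07, with 0 of 73 past the test and 3 at an unadjusted p under 0.05.

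Camera called these 5 lists at its preset correlation, with adjusted p of 3.21e-08 (mitochondrially encoded), 1.9e-06 (proliferation), 0.00388 (interferon), 0.00949 (inflammatory cytokines) and 0.0113 (oxidative phosphorylation). Each of the 5 calls was lost with an estimated correlation (adjusted p = 0.917 for each). The oxidative phosphorylation median was −0.00855 with date as a term, 0.00266 against the 5 controls of shared dates and 0.11 with the TPM share outside the table as a covariate. The mitochondrially encoded median was −0.22 against shared-date controls and 0.0287 with that covariate, which also took the ribosomal median from −0.05 to 0.12. The inflammatory cytokine median was 0.0316 against shared-date controls and −0.0548 against the 4 WT controls of 2 weeks. For proliferation and interferon genes, WT controls of date code 0810 had medians of −0.39 and −0.52 relative to WT controls of other dates. Controls of that code are part of the control group here, so control date may add to both early rises. Over all 13501 genes, 1703 had an unadjusted p under 0.05 by edgeR, DESeq2 called 138 genes, and edgeR with date as a term or against the 5 controls of shared dates called 0. Against the 6 rNLS8 controls alone it called 735, among them Tmem119 (−0.43, adjusted p = 0.0193), Apoe (2.54, 0.00696), Mki67 (2.57, 0.0492) and mt-Nd4 (−0.76, 0.0119), but all 6 have the date code 0810 and no early library has it. The Akap9 change was −0.38 in the fit with date as a term (adjusted p = 1), −0.49 against the 5 controls of shared dates (adjusted p = 1) and −0.69 against the rNLS8 controls (adjusted p = 0.00398). Its call ended when any one of Controls 1, 4, 5, 8, 9 and 11 or EarlyDisease 1, 4, 5, 6, 7 and 8 was left out (highest adjusted p = 0.129), and counts with 1 library left out ran from 0 to 77, the latter without Control 13.

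Late disease was compared with control to ask which genes differ once degeneration is advanced. The disease-associated microglia list, genes raised in microglia around damaged neurons, had 20 of 30 genes that rose and 0 that fell, and 21 that rose adjusted over the list alone, with a median log2 change of 1.06. Csf1 (ENSMUSG00000014599.8, chromosome 3, 107741048 to 107760469), the main growth factor of macrophages, rose by 2.57 ± 0.23 (SE), from 18.5 ± 8.05 CPM in controls (SD, n = 14) to 105 ± 29.4 CPM (n = 7), with an adjusted p of 4.12e-09 by edgeR. Spp1, which encodes osteopontin, rose by 3.19 ± 0.42 (adjusted p = 5.83e-06 by edgeR), and the phagocytic receptor gene Axl by 2.59 ± 0.32 (adjusted p = 2.15e-06). Apoe (ENSMUSG00000002985.13, chromosome 7, 19696109 to 19699188), a lipid carrier, rose by 4.03 ± 0.59, from 196 ± 292 to 3357 ± 3534 CPM, and Trem2 differed by −0.18 ± 0.12 (edgeR adjusted p = 3e-05 and 0.329). Camera called the list with an adjusted p of 5.25e-14, and the call was lost with an adjusted p = 0.0592 with an estimated correlation.

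Immune signalling genes were higher as well. Of 24 inflammatory cytokine and NF-kB genes, 15 rose and 1, Nfkb1, fell, against 16 and 1 adjusted over the list alone. The chemokine genes Ccl3, Ccl4 and Ccl5 rose by 2.37 ± 0.32, 1.97 ± 0.32 and 2.92 ± 0.40. Of 30 interferon response genes, 17 rose (21 adjusted over the list alone), among them the chemokine gene Cxcl10 by 3.00 ± 0.60 and Ifitm3, an antiviral membrane protein, by 1.92 ± 0.36. Antigen presentation genes rose in 7 of 22 cases (9 adjusted over the list alone), with the class II invariant chain Cd74 at 254 ± 102 against 66.4 ± 22.1 CPM and H2-Aa at 17.2 ± 11.3 against 3.03 ± 2.45 CPM. Camera gave adjusted p of 7.61e-09, 5.37e-09 and 0.000126 for the 3 lists, and none kept its call (adjusted p = 0.0592, 0.334 and 0.195 with an estimated correlation). Lysosome and phagocytosis genes numbered 12 that rose and 1 that fell of 32 (14 and 1 adjusted over the list alone). The scavenger receptor Msr1 rose by 3.15 ± 0.42 and the lysosomal enzyme gene Gusb by 0.41 ± 0.07, whereas the lysosomal membrane gene Laptm5 fell. Lipid efflux and storage genes rose in 7 of 18 cases (8 adjusted over the list alone, where 1 fell), including Ch25h by 2.40 ± 0.53. These lists were called with adjusted p of 0.00293 and 0.0109, and lost with adjusted p = 0.425 and 0.0592 with an estimated correlation.

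Homeostatic microglia genes moved in the other direction: 11 of 30 fell and 0 rose, with 19 falling adjusted over the list alone and a median of −0.35. Tmem119 (ENSMUSG00000054675.5, chromosome 5, 113793729 to 113800516) fell by 0.72 ± 0.09, from 8226 ± 859 to 4961 ± 977 CPM, with an adjusted p of 2.98e-06 by edgeR. Selplg fell by 0.60 ± 0.08, the purinergic receptor gene P2ry12 by 0.62 ± 0.15 and the fractalkine receptor gene Cx3cr1 by 0.46 ± 0.15. Camera called the list (adjusted p = 7.61e-09), and the call was lost with an adjusted p = 0.119 with an estimated correlation. The Cx3cr1 call ended when any one of Controls 5, 8, 10 and 11 or LateDisease 2 and 3 was left out. Among 18 unfolded protein response genes 7 fell and 2 rose (9 and 3 adjusted over the list alone), and camera did not call the list (adjusted p = 0.0599). Its transcription factor Xbp1 fell by 0.52 ± 0.11 and the chaperone partner Dnajb9 by 0.58 ± 0.14. The shear-responsive transcription factor Klf2 fell by 1.89 ± 0.28 and the tubulin gene Tuba1a by 1.06 ± 0.16. Both directions were seen among 27 immediate early and stress genes, of which 12 rose, including Ier3 (3.20 ± 0.44), and 6 fell, including Klf2 and the chaperone partner Dnajb1 (−0.81 ± 0.11), with 15 and 6 adjusted over the list alone. Ribosomal protein genes rose in 46 of 85 cases (60 adjusted over the list alone, where 1 fell), with a median of 0.42 and with Rpl10a at 81.3 ± 26.9 against 40.1 ± 7.33 CPM. That list was called with an adjusted p of 2.41e-12 and lost with an adjusted p = 0.425 with an estimated correlation.

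One library, LateDisease 6, stood apart in several of these groups. Its homeostatic list mean was 8.87 log2 CPM where the other 6 late libraries spanned 9.74 to 10.4, and its ribosomal list mean was 6.65 where they spanned 5.40 to 5.94. Without it, the change of the complement gene C4b went from 4.54 to 1.94, that of the antioxidant enzyme gene Gpx3 from 5.04 to 2.69, Ier3 from 3.20 to 2.10, Fn1 from 4.25 to 3.50, Msr1 from 3.15 to 2.48 and Apoe from 4.03 to 3.41, all still past the edgeR test. Leaving out Control 11 raised the Apoe change to 4.88. C4b has a near-identical neighbour, and its count may include reads of that copy.

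Complement genes rose in 3 of 14 cases by edgeR (4 adjusted over the list alone), C4b, C3 and Cfb, the last by 3.99 and by 5.35 without Control 10. Cholesterol synthesis genes fell in 3 of 24 cases (3 adjusted over the list alone), among them Ebp. Glycolysis genes rose in 3 of 20 cases (3 adjusted over the list alone), TGF-beta targets in 2 of 13 (5, with 1 falling) and growth factors in 2 of 11 (2), Igf1 and Vegfa. Of 14 p53 and apoptosis genes, 2 rose, among them the death effector gene Bax, and 1 fell (5 and 1 adjusted over the list alone). Proliferation genes Mcm7 and Birc5 rose, 2 of 40 (0 adjusted over the list alone), and Mki67 was at 5.45 ± 4.48 against 1.94 ± 2.53 CPM (adjusted p = 0.172 by edgeR). Camera called the proliferation list (adjusted p = 0.000195), which was lost with an adjusted p = 0.425 with an estimated correlation. The Mcm7 call ended without LateDisease 6 and the Birc5 call without Control 8 or LateDisease 2, 3, 5 or 7.

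Markers of other cells were few among the changed genes. Monocyte markers rose in 3 of 11 cases (3 adjusted over the list alone), among them Fn1 and Ms4a4c, and border macrophage markers in 1 of 12 (4), Siglec1 by 2.13 ± 0.54. The border macrophage list was called (adjusted p = 0.039) and lost with an adjusted p = 0.425 with an estimated correlation. Neutrophil, endothelial and oligodendrocyte markers had 1 gene each that rose, Csf3r of 13, Flt1 of 5 and Trf of 7, each also 1 adjusted over the list alone. Astrocyte, neuron, B cell and erythroid markers had 0 of 7, 3, 3 and 3 genes past the edgeR test, and 0, 0, 0 and 3 at an unadjusted p under 0.05. The 3 erythroid genes fell adjusted over the list alone. Erythroid list means were −0.88 ± 3.36 log2 CPM in controls and −1.71 ± 1.46 in late disease (SD). The control level rested mostly on Controls 8, 12 and 13, at 5.18, 4.92 and 5.36. Nuclear-encoded oxidative phosphorylation and mitochondrially encoded genes had 0 of 73 and 0 of 13, and 7 and 0 at an unadjusted p under 0.05. Mouse Tardbp, the gene of TDP-43, differed by 0.39 ± 0.20 (adjusted p = 0.184 by edgeR).

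In all, 2080 genes differed between late disease and control, 1217 higher and 863 lower, with 342 and 43 of them by at least 2-fold. Date codes were unevenly spread over these groups. Against the 5 controls of the dates that late disease shares, edgeR called 191 genes, 172 of them among the 2080. With date as a term it called 18, of which 17 were among them. In these 2 fits 2075 of 2076 and 2061 of 2080 called genes kept their direction, with the same late libraries in each. Their median standard error was 0.178 and 0.217, in place of 0.145 in the main fit. In the fit with date as a term Csf1 rose by 2.37 (adjusted p = 0.00193), Cd74 by 1.99 (0.0222), Axl by 2.17 (0.043), Msr1 by 3.22 (0.043) and Rpl10a by 0.83 (0.043), and Selplg fell by 0.62 (0.043), and these were the 6 of 61 named genes that kept their call. Spp1, Apoe, Tmem119 and P2ry12 had changes of 2.91, 2.75, −0.54 and −0.58 there (edgeR adjusted p = 0.0616, 0.0622, 0.105 and 0.369). List medians with date as a term were 0.66 for disease-associated, 1.30 for interferon, 0.63 for inflammatory cytokine, 0.53 for antigen presentation, −0.37 for homeostatic and 0.38 for ribosomal protein genes. Counts fell to 1327 without LateDisease 3 and 1376 without LateDisease 6.

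**Figure D2:**
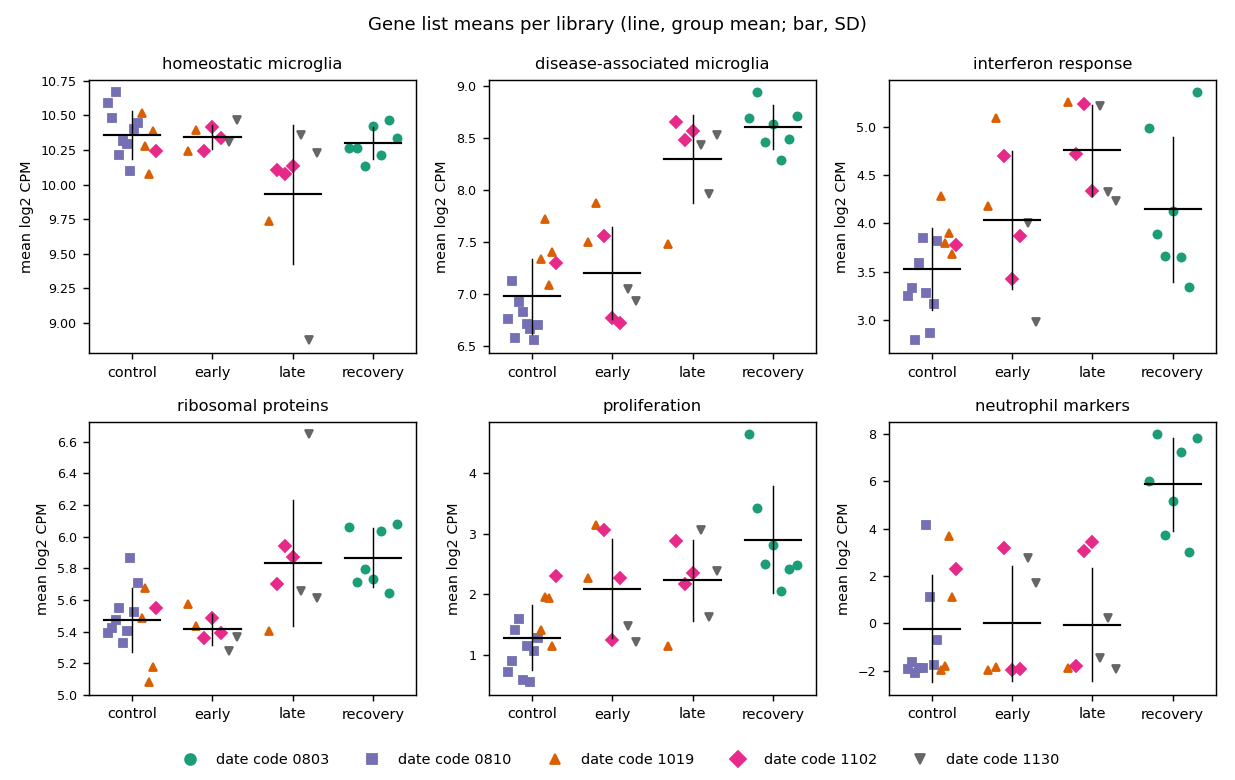
Mean log2 CPM of 6 gene lists in each library (points, coloured by date code), with the group mean (line) and SD (bar). The 7 recovery libraries hold neutrophil markers at 3.03 to 7.98, and LateDisease 6 is the lowest point of the homeostatic list and the highest of the ribosomal list.

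Recovery was compared with control to ask which differences were present 1 week after the transgene was silenced again. The largest rises were in genes of neutrophils and monocytes. Of 13 neutrophil markers, 12 rose (13 adjusted over the list alone), with a median log2 change of 5.34. The granule protein gene Camp rose by 6.74 ± 1.08 and Lcn2 by 6.08 ± 1.04. S100a9, an abundant neutrophil calcium-binding protein, was at 577 ± 584 CPM (SD, n = 7) against 10.9 ± 17.2 (n = 14), and Ngp at 840 ± 850 against 13.8 ± 25.0 CPM. Of 11 monocyte markers, 8 rose (9 adjusted over the list alone), with a median of 3.81, including Chil3 (ENSMUSG00000040809.10, chromosome 3, 106147554 to 106167564) by 8.11 ± 1.07 and Ly6c2, which has a close paralog, by 6.60 ± 0.95. Camera called both lists at the preset correlation (adjusted p = 3.88e-24 and 2.69e-16) and with an estimated one (adjusted p = 0.00588 and 0.000801 with an estimated correlation). The neutrophil list mean was 5.86 ± 1.97 log2 CPM in recovery and −0.23 ± 2.26 in controls, and it ran from 3.03 in Recovery 8 to 7.98 in Recovery 3. Among controls the highest mean, 4.17, was in Control 6, and without that library the S100a9 change was 8.56 in place of 5.88. Without Control 6 the changes of Camp, Ngp, Chil3, Lcn2 and Ly6c2 were 8.37, 9.74, 8.84, 7.94 and 7.59. Without Recovery 3 those of Camp, S100a9, Ngp, Chil3, Lcn2 and Ly6c2 were 5.54, 4.78, 4.74, 6.88, 5.24 and 5.76.

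The disease-associated microglia list rose in recovery too, with 20 of 30 genes (26 adjusted over the list alone), 0 that fell and a median of 1.11. Csf1 rose by 2.29 ± 0.23 (adjusted p = 5.13e-08 by edgeR), Spp1 by 3.78 ± 0.43 (adjusted p = 1.13e-06), the galectin gene Lgals3 by 2.69 ± 0.31 (adjusted p = 1.34e-06) and Apoe by 3.60 ± 0.58 (adjusted p = 0.000138). Without Control 11 the Apoe change was 4.32. Antigen presentation genes rose in 4 of 22 cases (7 adjusted over the list alone). Cd74 (ENSMUSG00000024610.12, chromosome 18, 60803848 to 60812652) was at 371 ± 63.0 against 66.4 ± 22.1 CPM, and H2-Aa and H2-Ab1, which encode class II chains, rose by 3.74 ± 0.48 and 2.15 ± 0.29. Of 40 proliferation genes 21 rose (34 adjusted over the list alone), with a median of 1.81, including Birc5 by 2.76 ± 0.55 and the nucleotide-synthesis gene Rrm2 by 2.13 ± 0.48, and Mki67 was at 10.6 ± 11.6 against 1.94 ± 2.53 CPM (adjusted p = 0.0537 by edgeR). The Rrm2 call ended without Recovery 2. Inflammatory cytokine genes rose in 6 of 24 cases (9 adjusted over the list alone), with Ccl3 and Ccl4 up by 2.44 ± 0.32 and 2.14 ± 0.32. These 4 lists were called at the preset correlation (adjusted p = 5.15e-32, 4.86e-07, 4.67e-20 and 1.05e-07) and kept their calls (adjusted p = 0.0015, 0.0308, 0.0252 and 0.0252 with an estimated correlation).

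Further lists called in recovery under both correlations were lipid efflux and storage, glycolysis, growth factors, border macrophage and endothelial markers. Lipid genes rose in 3 of 18 cases (4 adjusted over the list alone), including the cholesterol hydroxylase gene Ch25h (3.48 ± 0.55), and glycolysis genes in 6 of 20 (10), including pyruvate kinase Pkm (0.59 ± 0.09). Growth factors rose in 2 of 11 cases (3), Igf1 by 4.25 ± 0.66 and Vegfa by 4.44 ± 0.82, at low levels of 9.35 ± 4.58 and 1.75 ± 1.44 CPM, and Vegfa by 5.16 without Control 14. Border macrophage markers rose in 2 of 12 cases (6) and endothelial markers in 3 of 5 (3, with 1 falling), Pglyrp1, Flt1 and Slc2a1, of which Pglyrp1 is also abundant in neutrophils. The Slc2a1 call ended without Recovery 2, 7 or 9, and Pglyrp1 rose by 5.29, by 7.10 without Control 6 and by 4.57 without Recovery 3. Their adjusted p were 0.00227, 0.0308, 0.0308, 0.0444 and 0.0252 with an estimated correlation. The lists of lysosome (7 of 32 rose, 11 adjusted over the list alone), complement (2 of 14, 3), interferon (2 of 30, 7), ribosomal (23 of 85, 67) and nuclear-encoded oxidative phosphorylation genes (3 of 73, 5) were called at the preset correlation alone, with adjusted p = 0.111, 0.0601, 0.464, 0.0848 and 0.314 with an estimated correlation. Ifitm3 rose by 1.88 ± 0.36, and by 1.28 without Recovery 9. Homeostatic genes had 0 of 30 past the edgeR test, 6 at an unadjusted p under 0.05, all lower, and a median of −0.16. Their list was called lower (adjusted p = 0.00301) and lost with an adjusted p = 0.335 with an estimated correlation. Immediate early and stress genes rose in 4 of 27 cases and Dnajb1 fell (4 and 4 adjusted over the list alone), and Bambi alone rose of 13 TGF-beta targets (1). Named genes that fell in recovery included the polarity gene Pard3b (−1.16 ± 0.26), Disc1 (−0.94 ± 0.20) and Hmbox1 (−0.91 ± 0.18).

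In total 537 genes differed in recovery, 388 higher and 149 lower, with 235 and 20 by at least 2-fold. All recovery libraries share a date code that no other library has, so recovery and date cannot be told apart in these data. Counts were 341 without Recovery 2 and 329 without Recovery 9. With the neutrophil list mean as a covariate, chosen after the data were seen, 4 genes stayed past the edgeR test: Csf1 (2.18, adjusted p = 0.00664), Cd74 (2.24, 0.00664), Lgals3 (3.21, 0.00664) and Spp1 (3.78, 0.00966). That covariate took the list medians from 1.11 to 0.97 for disease-associated, 1.81 to 1.52 for proliferation, 0.33 to 0.20 for antigen presentation, 0.54 to 0.19 for inflammatory cytokine, 0.25 to 0.13 for lipid and 3.81 to 0.74 for monocyte genes. It took them from 1.37 to 1.34 for border macrophage, 0.65 to 0.68 for growth factor, 0.34 to 0.29 for glycolysis and 0.19 to 0.16 for lysosome genes, and these 10 lists were all still called by camera at the preset correlation. The calls of the complement and homeostatic lists ended with it (adjusted p = 0.114 and 0.282).

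**Figure D3:**
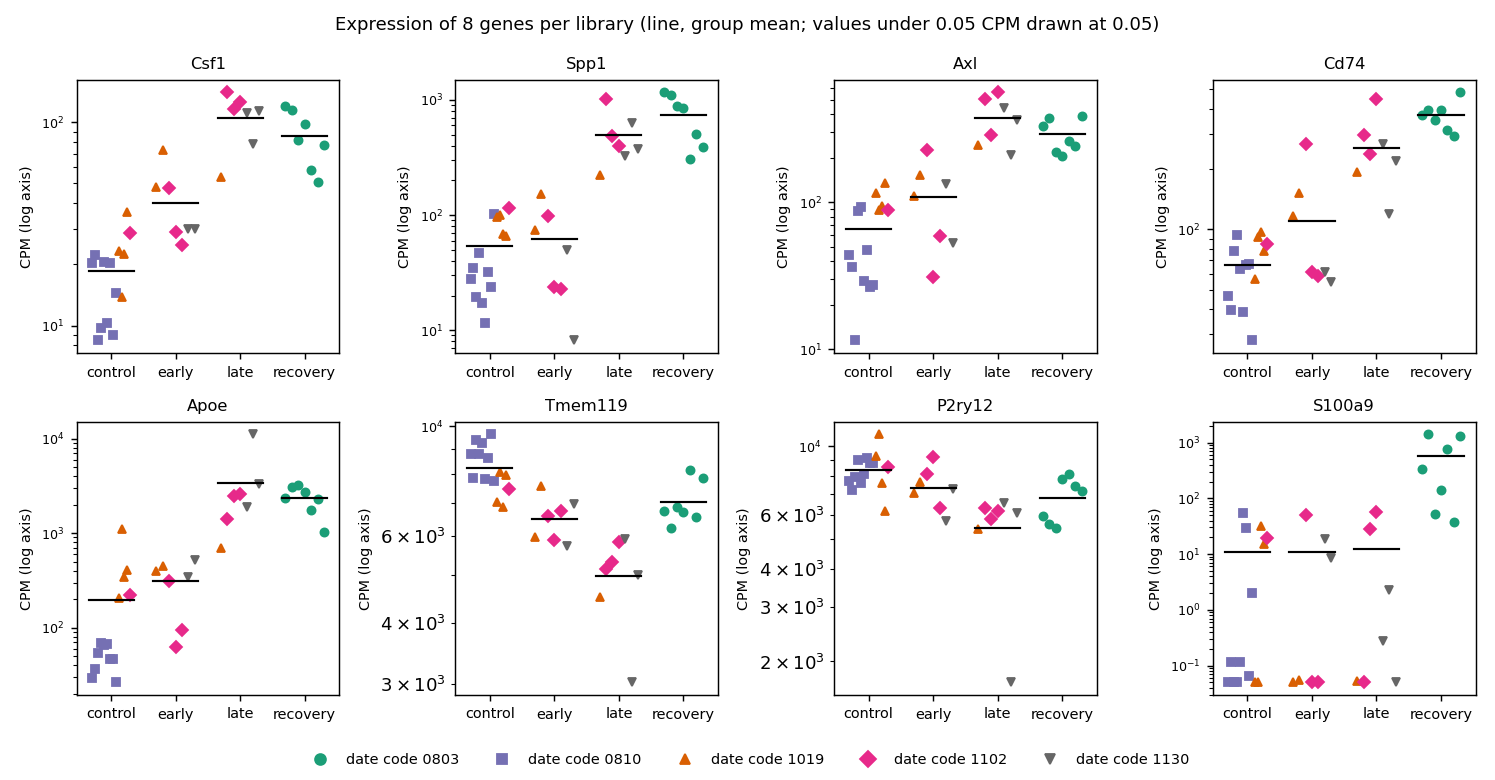
CPM of 8 genes in each library on a log axis, coloured by date code, with the group mean as a line and values under 0.05 CPM drawn at 0.05. Csf1 averages 18.5 CPM in controls, 105 in late disease and 85.8 in recovery, and S100a9 averages 577 CPM in recovery and at most 12.5 in the other groups.

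Late and early disease shared 3 date codes and were compared directly to ask what changed between 2 and 6 weeks. Genes of the disease-associated list rose in 10 of 30 cases (19 adjusted over the list alone), with a median log2 change of 0.74, among them Spp1 from 61.4 ± 51.4 to 496 ± 267 CPM (SD, n = 7 each), the protease inhibitor gene Cst7 by 2.52 ± 0.51 and Csf1 by 1.43 ± 0.27. Apoe rose by 3.24 ± 0.77 and the fibronectin gene Fn1 by 3.58 ± 0.68. Of 22 antigen presentation genes 3 rose (10 adjusted over the list alone), Cd74 by 1.27 ± 0.29, H2-D1 by 1.17 ± 0.28 and H2-Aa by 2.35 ± 0.59. The lists of disease-associated, antigen presentation and lipid genes (1 of 18 rose, 4 adjusted over the list alone) were called with adjusted p of 5.56e-23, 8.39e-11 and 0.00364, and kept their calls (adjusted p = 0.0161, 0.0161 and 0.0179 with an estimated correlation). Inflammatory cytokine genes rose in 3 of 24 cases (10, with 1 falling), including Ccl5, and lysosome genes in 4 of 32 (12). Among ribosomal protein genes 5 of 85 rose (66, with 1 falling), with a median of 0.50, or 0.30 without LateDisease 6. The 13 mitochondrially encoded genes had 0 past the edgeR test, 12 at an unadjusted p under 0.05 and 11 that rose adjusted over the list alone. Klf2 fell by 1.40 ± 0.30, Tuba1a by 0.82 ± 0.18 and Selplg by 0.38 ± 0.09, the single homeostatic gene of 30 past the test (4 adjusted over the list alone).

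The lists of ribosomal, homeostatic (lower), mitochondrially encoded, lysosome, inflammatory cytokine, interferon (0 of 30, 2 adjusted over the list alone, 5 at an unadjusted p under 0.05 by edgeR), complement (0 of 14, 3), TGF-beta target (1 of 13, 1) and oxidative phosphorylation genes (0 of 73, 0, with 5 at an unadjusted p under 0.05) were called at the preset correlation alone. Their adjusted p were 0.107, 0.0998, 0.187, 0.0998, 0.0648, 0.326, 0.19, 0.107 and 0.705 with an estimated correlation. Without LateDisease 6 and Control 7 the oxidative phosphorylation median was 0.00819 in place of 0.08 and its call ended (adjusted p = 0.717), and the homeostatic median was −0.15 in place of −0.23. The oxidative phosphorylation call also ended without LateDisease 4, LateDisease 6 or EarlyDisease 7 alone, and the complement call without LateDisease 4 or 5. In total 81 genes rose and 19 fell between early and late disease. With date as a term 85 genes passed, and 23 of the 33 named genes kept their call, among them Spp1 (3.26, edgeR adjusted p = 0.00589), Apoe (3.37, 0.00118), Cst7 (2.60, 0.00589) and Csf1 (1.54, 0.00697). Counts with 1 library left out ran from 16 without EarlyDisease 6 to 235 without LateDisease 7, and without EarlyDisease 6 just 7 of the 33 named genes stayed past the test. Single libraries ended the calls of Klf2 (EarlyDisease 6, LateDisease 3), Tuba1a (EarlyDisease 5, 6, 8, LateDisease 3) and Cd74 (EarlyDisease 5 to 8, LateDisease 3, 4). The same held for Apoe (any early library, LateDisease 3, 6), Selplg (any early library, LateDisease 1, 2, 3, 6), H2-Aa (EarlyDisease 1, 3, 5 to 8, LateDisease 2, 3, 4) and H2-D1 (EarlyDisease 1, 3, 5 to 8, LateDisease 2, 3, 6). Fn1 rose by 2.85 without LateDisease 6. A fit of these 2 groups alone called 15 genes.

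Recovery and late disease were compared to ask what differed after 1 week back on doxycycline. Tmem119 rose by 0.49 ± 0.10, from 4961 ± 977 to 7010 ± 710 CPM (SD, n = 7 each; edgeR adjusted p = 0.028), and Selplg by 0.40 ± 0.09 (edgeR adjusted p = 0.0405), 2 of 30 homeostatic genes (3 adjusted over the list alone). Klf2, singled out here after its values were seen, was at 44.4 ± 12.1 against 18.3 ± 6.25 CPM and rose by 1.23 ± 0.30. Neutrophil markers rose in 5 of 13 cases (12 adjusted over the list alone) and monocyte markers in 4 of 11 (8), including Ly6c2 by 6.95 ± 1.31 and Camp by 6.29 ± 1.43. The cold-inducible RNA-binding protein gene Cirbp fell by 1.61 ± 0.36, from 115 ± 90.2 to 37.0 ± 13.4 CPM, and the repair gene Uvssa by 1.39 ± 0.31. Disease-associated genes had 0 of 30 past the edgeR test (3 at an unadjusted p under 0.05) and a median of 0.22, and Apoe, at 2357 ± 767 against 3357 ± 3534 CPM, differed by −0.43 ± 0.69 (adjusted p = 0.819 by edgeR).

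The neutrophil and monocyte lists were called under both correlations (adjusted p = 0.0343 and 0.0269 with an estimated correlation). The lists of homeostatic (median 0.22), proliferation (0.91, 0 of 40 genes past edgeR and 7 at an unadjusted p under 0.05), oxidative phosphorylation (0 of 73, 14 at an unadjusted p under 0.05), unfolded protein response (0 of 18, 7 that rose adjusted over the list alone), glycolysis (0 of 20, 2 that rose and 2 that fell adjusted over the list alone) and disease-associated genes were called higher, and interferon genes (−0.32, 0 of 30 past edgeR and 6 at an unadjusted p under 0.05) lower, at the preset correlation alone. Their adjusted p were 0.514, 0.599, 0.599, 0.599, 0.599, 0.739 and 0.599 with an estimated correlation. In total 46 genes rose and 33 fell. The count ran from 6 without Recovery 3 to 223 without LateDisease 5, and no date code holds both groups, so date and group cannot be told apart. The Tmem119 and Selplg calls also ended with the neutrophil mean as a covariate (0.59 and 0.49, edgeR adjusted p = 0.106 and 0.112) and with the TPM share as one (0.41 and 0.38, adjusted p = 0.0772 and 0.0922), as did those of Cirbp and Uvssa (edgeR adjusted p = 0.0587 and 0.144, then 0.0922 and 0.0979). Cirbp and Uvssa stayed lower in recovery with either covariate. With the neutrophil mean the proliferation median was 0.57, and the calls of the proliferation, glycolysis and disease-associated lists ended (adjusted p = 0.0526, 0.199 and 0.199). The glycolysis median was then 0.135 in place of 0.173, and the disease-associated median was larger, at 0.314 in place of 0.223. The Tmem119 call ended without any one of Recovery 3, 7 and 9 or LateDisease 1 and 3, and the Selplg call without Recovery 2, 3, 7 or 9 or LateDisease 1, 2, 3 or 6. The Cirbp call ended without Recovery 2, 3, 7 or 9 or LateDisease 1, 3 or 6, and the Uvssa call without Recovery 2, 3, 5, 7 or 9 or LateDisease 1 or 3. Without Recovery 3 Ly6c2 differed by 6.18 and Camp by 5.30, past the test in neither case, and without LateDisease 4 they rose by 7.97 and 7.20. The Camp call also ended without Recovery 2, 7 or 9 or LateDisease 1, 3, 6 or 7.

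Fold changes of late disease and of recovery were then set side by side, each against controls of its own that the other did not use (5 and 9). Across 12241 genes, which are not independent replicates, the Pearson correlation was 0.37, Spearman's 0.28 and the covariance 0.108. In 20 simulations of unchanged groups the mean correlation was −0.01, the highest 0.03 and the mean covariance −0.000761. Those simulations drew genes independently and with no date effect, so they leave out what real libraries share. They cannot show whether 0.37 is more than unchanged real libraries would give. With all 14 controls in both, the correlation was 0.61 and the covariance 0.17, where unchanged groups gave 0.35 and 0.0401. Of the 1217 and 388 genes that rose in late disease and in recovery 214 were in both, against 35 for independent lists, and of the 863 and 149 that fell 53 were in both, against 9.52. The shared controls add to those overlaps. With separate controls 6 genes rose in late disease, and all 6 were among the 449 that rose in recovery, while 0 fell in late disease and 348 in recovery. That late fit held 12 libraries, the late ones and 5 controls, and counted genes tested in both fits. The fit that called 191 genes against the same 5 controls took its variance from all 4 groups.

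The 2 kinds of control were compared to learn whether they differ. One gene of 12425 passed the edgeR test between the 6 rNLS8 mice on doxycycline and the 8 WT mice: Pttg1, the securin gene, fell by 3.06 ± 0.41 (adjusted p = 0.0125), and 930 genes had an unadjusted p under 0.05. DESeq2 called 27. Camera called 5 of 26 lists at the preset correlation, with mitochondrially encoded (adjusted p = 9.06e-12), ribosomal (8.01e-05), oxidative phosphorylation (0.000543) and unfolded protein response genes (0.039) higher and B cell markers (0.0414) lower in the rNLS8 mice. With an estimated correlation 0 of the 26 lists kept a call (adjusted p = 0.467 for mitochondrially encoded genes and 0.826 for each of the other 4). All 6 rNLS8 controls and 3 of the 8 WT controls have the date code 0810. The count was 0 without Control 5 or Control 9, 2 without Control 4, 8 or 13, 3 without Control 14 and 4 without Control 6.

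Whether changes differed between females and males was tested with an interaction term. By edgeR 0 genes of 14514 passed for early disease, late disease or recovery against control, with 383, 722 and 782 at an unadjusted p under 0.05 and smallest adjusted p of 1, 0.485 and 0.36. That test used the sex in the labels, which Xist and Ddx3y counts contradict in Controls 7 and 8. With the sex of the design table, which those counts match, 0 genes passed as well, with 559, 1003 and 1196 at an unadjusted p under 0.05 and smallest adjusted p of 0.918, 0.495 and 0.117 by edgeR. In simulated data with the same group sizes the test recovered 62.5%, 59.7% and 67.3% of genes whose change differed 4-fold between the sexes, and 20.7%, 15% and 29.2% of those that differed 2-fold.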

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

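Chosen only after the results were seen were the test on early disease of the shared dates, the leave-one-out ranges of the ratios below, the count of neutrophil markers and the test of the recovery date. The bounds of the other tests were written before their results.

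Among 210 checks of single libraries within 5 groups of 4 to 7, 17 showed 1 library far from the others by Dixon's ratio, and chance flags about 1 in 20. LateDisease 6 accounted for 6 of them. Its log2 CPM was 10.7 for P2ry12 (other late libraries 12.4 to 12.7), 11.6 for Tmem119 (12.1 to 12.5) and 10.2 for Cx3cr1 (12.3 to 12.7). Its list means were 8.87 for homeostatic (9.74 to 10.4), 6.65 for ribosomal (5.40 to 5.94) and 3.34 for B cell genes (5.18 to 5.98). LateDisease 1 had 23.3% of its counts in its 50 highest genes (27.6 to 30.0), Tardbp at 7.24 (5.19 to 6.02), lipid efflux and storage genes at 3.65 (4.31 to 4.48) and glycolysis genes at 5.90 (6.26 to 6.45). Erythroid means were 0.97 in EarlyDisease 5 (others −3.10 to −1.79), 4.70 in Recovery 3 (−3.10 to −2.04) and 5.18 in Control 8 (−3.10 to −1.89, rNLS8 controls on doxycycline). Recovery 4 had an unfolded protein response mean of 6.25 (6.87 to 7.27). Among the same 6 controls, Control 6 had a monocyte mean of 0.59 (−1.04 to −0.73), and Control 7 had a B cell mean of 3.55 (5.15 to 5.63) and Trem2 at 10.7 (10.2 to 10.4).

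The first pattern weighed is the 2080 genes that differed between late disease and control. Against the 5 controls of shared dates their median signed change was 0.788 of that against all 14, which met the bound of 0.75 set beforehand for date not being the cause, but the range with 1 of the 12 libraries left out, added once that was seen, crossed the bound (0.649 to 0.848) and turned the verdict, so the share owed to date stays open (0.743 with date as a term). In early disease, whose libraries have the same dates, these genes moved by 0.382 of the late change against the same 14 controls. That ratio (0.351 to 0.449 with 1 library left out) was below the bound of 0.5 set against control date as the whole cause. But the genes were chosen for their late change, which by itself lowers the ratio. In early disease 1884 of the 2080 moved in the same direction. The ratio therefore cannot decide whether control date is the whole cause. With the TPM share outside the table as a covariate the ratio was 0.647, between its bounds of 0.25 and 0.75, but RNA input was not measured and the share differed by control date (18.3% on average in the 0810 controls, 4.99% in other libraries). What that share reflects therefore cannot be told apart from disease for part of the change, and disease stage remains open beside date.

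The second pattern is the rise of neutrophil and monocyte genes in recovery. Of 13 neutrophil markers 12 rose. RNA of such cells in the sorted fraction is a candidate source, since the CD11b and CD45 gate alone could admit them, but that count is the pattern itself and no separate test of its source, which stays open. With 0 libraries of other groups on the recovery date, that date cannot be told apart from recovery. With the neutrophil mean as a covariate the disease-associated list kept 0.877 of its median (0.803 to 0.979 with 1 library left out). That argues against neutrophil RNA as the whole source of the list's rise, though neutrophil means of recovery and controls overlapped little. Recovery 4 and 8, with neutrophil means of 3.73 and 3.03, had disease-associated means of 8.47 and 8.49. Control 6, with a neutrophil mean of 4.17, had 6.71. Monocyte RNA was not tested as a source of that list's rise. Other medians changed unevenly (growth factors 0.65 to 0.68, proliferation 1.81 to 1.52, inflammatory cytokine 0.54 to 0.19, monocyte 3.81 to 0.74) and were not weighed.

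The third pattern is the rise of ribosomal protein genes between early and late disease. With date as a term the list median kept 0.888 of its size (0.818 to 0.993 with 1 library left out), which argues against date as the cause. Without LateDisease 6 it kept 0.603, from 0.497 to 0.300, between its bounds of 0.25 and 0.75, so a part that may rest on that library cannot be told apart from the rest. Disease stage was not tested apart from these.

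Other splits of the same libraries were drawn without regard to date, 100 per comparison with the real one included. They were fitted to ask whether chance can be excluded. It could be excluded for the gene counts of late disease (2080, highest other 54), recovery (537, highest other 40), late against early disease (100, highest other 11) and recovery against late disease (79, highest other 9), in each of which 1 split, the real one, gave as many. It could be excluded for the lists called in recovery (17, with 2 splits giving as many and the highest other also 17). It could not be excluded for the gene of early disease (12 splits with as many, highest other 20) or for lists called in early disease (5, 49 splits, highest 13), late disease (10, 12 splits, highest 16), late against early disease (12, 26 splits, highest 18) and recovery against late disease (9, 63 splits, highest 18). Nor could it be for the gene between the kinds of control (5 splits, highest 3). In late disease against control and in both comparisons of recovery, the real groups also follow date codes. There, excluding chance does not tell group from date. For sex the real counts were 0, which every split reaches (100 splits each, highest 1, 74 and 1), so these splits say nothing of chance. The 20 genes of one split in early disease, against a real count of 1, point to a structure of the samples. It may be date or no more than 1 unusual library, and what it is was not tested. Most libraries placed as early disease in that split have the code 0810, but another split of the same date makeup called 0 genes.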

How the results depend on the processing

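Chosen after the data were seen were early disease against shared-date controls, leaving out LateDisease 6 with Control 7, the 2 covariates and the rescaled TPM. Of 13227 values of single genes and lists, 22 reversed, where the direction of a list is that of camera's test. In 4 of the 22 the list's median kept its sign. The cause was not tested unless a sentence names it. Size factors of another method, no sex term and the sex of the design table moved no count by over 1.5 times. In simulated data small changes were missed most: in early disease edgeR recovered 44.1% at a fold of 1.5 and 77.9% at a fold of 4.

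Gene counts in early disease (1) were 0 with no filter, with date as a term, against the WT controls of 2 weeks, against shared-date controls and with the TPM share as a covariate, 3 without LateDisease 6 and Control 7, 7 with the neutrophil mean, 4 on rescaled TPM, 138 by DESeq2, 735 against rNLS8 controls, 1390 on log2 TPM + 1 (1343 higher, 47 lower) and 1354 on log2 TPM + 0.1. Lists (5) were 9 in a fit of 2 groups, 8 with date as a term, 3 against WT controls of 2 weeks and 3 against shared-date controls. Columns of the deposited TPM fell short of the full total by 14.1% in controls and 4.35% in early disease on average. Rescaling them to a common total took 1390 genes to 4, so nearly all of those calls came from the column totals. In late disease (2080) counts were 959 in the fit of 2 groups, 18 with date as a term, 191 against shared-date controls, 1272 without LateDisease 6 and Control 7, and 89 genes with 18 lists with the TPM share. On log2 TPM + 1 late disease had 2627 higher and 197 lower genes, against 1217 and 863 by edgeR. TPM columns of late disease fell short by 3.71% on average, so the same difference in totals from controls applies there. In recovery (537) counts were 966 against controls of code 0810, 895 without LateDisease 6 and Control 7, 4 with the neutrophil mean and 302 with the TPM share. Late against early disease (100) gave 51 with no filter, 356 by DESeq2, 15 in the fit of 2 groups, 44 without LateDisease 6 and Control 7, 180 with the TPM share and 172 on rescaled TPM. Recovery against late disease (79) gave 404 by DESeq2, 14 in the fit of 2 groups, 4 with the neutrophil mean, 19 with the TPM share and 144 on rescaled TPM. The kinds of control (1) gave 5 with no filter, 27 by DESeq2, and 4 and 3 on log2 TPM + 1 and + 0.1. With an estimated correlation the lists called were 0, 0, 11, 3 and 2 in the order early, late, recovery, late against early and recovery against late. The correlation of late and recovery changes (0.37) was 0.61 with all 14 controls in both and 0.63 over the 797 called genes.

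With the replicate number as a block, in fits of the 2 groups, early disease had 192 genes and 8 lists, late disease 135, recovery 278, and late against early and recovery against late 0 each by edgeR. Same-numbered libraries did not deviate together (r from −0.20 to 0.14, over 0.1 in 1 pair of 6 and 1 of 5 in the last 2 comparisons and in 0 pairs of 7 in the others), and libraries matched their own number best in at most 2 cases, so the numbers pair nothing.

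With 1 library left out, genes ran from 0 to 77 in early disease (lists 2 to 7), 1327 to 2265 in late disease (9 to 15), 329 to 747 in recovery (16 to 18), 16 to 235 in late against early disease (11 to 14), 6 to 223 in recovery against late disease (7 to 12) and 0 to 4 between controls.

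With date as a term Sesn2 turned to −0.00429 in late disease, and camera's direction turned for the neutrophil list in early and late disease and for oxidative phosphorylation in early disease, though their medians of −2.63, −2.80 and −0.00855 kept their sign. So did the early oxidative phosphorylation median of −0.00527 against WT controls of 2 weeks, where the inflammatory cytokine median turned to −0.0548. The former turned to 0.00266 against shared-date controls. Against rNLS8 controls the mitochondrially encoded median in recovery was −0.19, and 0.46 with the TPM share as a covariate, in place of 0.04. With the TPM share as a covariate the early medians were 0.12 for ribosomal, 0.11 for oxidative phosphorylation and 0.0287 for mitochondrially encoded genes. With the neutrophil mean as a covariate, which holds these genes by construction, recovery against control gave Camp −0.38, Serpinb1a −0.11, Ngp −0.70, S100a9 −1.05, Cd177 −0.0645, Pglyrp1 −0.75 and the list −0.86, and recovery against late disease gave Camp −0.0995, Wfdc21 −0.0989, Pglyrp1 −0.0909 and the list −0.27.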

Other observations

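The genes of the first paragraph and the comparison of WT controls by date were chosen after their values were seen, and the tests on heat-shock and glucocorticoid lists had their bounds written before their results, except the interval of the glucocorticoid median, which was added after. In late disease 2 cold-inducible RNA-binding protein genes rose, Cirbp by 2.39 ± 0.29 (SE) from 21.8 ± 8.36 to 115 ± 90.2 CPM (SD, n = 14 and 7, edgeR adjusted p = 1.96e-06) and Rbm3 by 1.81 ± 0.24 (edgeR adjusted p = 7.93e-06), in 7 of 7 late libraries above the control median. Rbm3 also rose in recovery, by 0.94 ± 0.25 (edgeR adjusted p = 0.022, 7 of 7 libraries), where Cirbp differed by 0.78 ± 0.30 (adjusted p = 0.141, 7 of 7). In early disease Rbm3 and Cirbp differed by 0.69 ± 0.25 and 0.62 ± 0.30 (edgeR adjusted p = 0.236 and 0.381, 7 and 6 of 7). Outside late disease most libraries thus stood above the control median for both genes, but Rbm3 in recovery alone passed the test. The chaperone partner genes Dnaja1 and Dnajb1 fell in late disease by 0.96 ± 0.13 and 0.81 ± 0.11, and in recovery by 0.48 ± 0.13 and 0.40 ± 0.11 (edgeR adjusted p = 0.0285 and 0.0344).

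Among WT controls, the 3 of date code 0810 and the 5 of other dates differed in 3 genes of 12772 by edgeR, all lower in the former, with 1207 at an unadjusted p under 0.05. Camera called 9 of 26 lists at the preset correlation, with neutrophil (median −7.41), inflammatory cytokine (−0.55), interferon (−0.52), proliferation (−0.39), cholesterol synthesis (−0.26) and disease-associated genes (−0.17) lower and mitochondrially encoded (0.25), homeostatic (0.12) and ribosomal genes (0.0968) higher in the 0810 controls. None kept its call, with adjusted p = 0.479, 0.121, 0.479, 0.678, 0.678, 0.678, 0.678, 0.298 and 0.754 with an estimated correlation. The neutrophil difference rests on Controls 12, 13 and 14, with list means of 3.69, 1.13 and 2.31 log2 CPM. Controls 10 and 11, also of other dates, were at −1.98 and −1.78. Controls 1, 2 and 3 of code 0810 were at −1.91, −1.62 and −2.08, but Control 6, an rNLS8 mouse of that code, was at 4.17.

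One hypothesis was that a lower temperature of the animal or tissue in late disease may lower heat-shock factor activity. Its gene list was written after the first results, so a test on the same libraries is not independent of them. The test took 22 heat-shock factor targets: 12 fell and 1, Hspa4, rose (14 and 1 adjusted over the list alone), the median was −0.37, and camera gave p = 8.43e-09, or p = 0.012 with an estimated correlation. Of these targets Hspa8, Hsph1 and Hspa1b are also in the immediate early and stress list, where their falls had been seen. The median was −0.25 against controls of shared dates and −0.28 with date as a term. In early disease and recovery 0 of the 22 targets passed the edgeR test. Dnaja1 and Dnajb1, which fell in recovery, were not among the 22. The medians were −0.15 and −0.17 in early disease and recovery, with camera p of 0.000398 and 0.000777, or 0.11 and 0.129 with an estimated correlation. Between early and late disease the median was −0.23 (0 genes past the test, camera p = 9.07e-06, or 0.048 with an estimated correlation). Lower medians were thus seen outside late disease as well. The late values are in line with the hypothesis, but temperature was not measured, and other causes of lower heat-shock factor activity, or of handling before the sort, would give the same values.

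A second hypothesis, less glucocorticoid signalling in late disease, came from the falls of Tsc22d3 and Klf2. Of 12 glucocorticoid-induced genes 5 rose and 2 fell (5 and 2 adjusted over the list alone) and the median was 0.70, over the bound of −0.1 set for rejecting it. But members went both ways, the 95% order-statistic interval of the median ran from −0.51 to 3.23, and camera gave p = 0.80 with a direction opposite to the median (0.901 with an estimated correlation), so the list leaves the hypothesis open. The median was 0.93 against controls of shared dates and 0.59 with date as a term. The Tsc22d3 call (−1.27 ± 0.41, edgeR adjusted p = 0.0311) ended without any one of LateDisease 1 to 5 and 7, and without LateDisease 6 the change was −2.01.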
